A study of Homo sapiens with 8 samples.

How the data were processed

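Affymetrix U133 Plus 2.0 arrays of 8 samples of transfected Reh cells were analysed. The groups came from the sample labels: mock, IRF5-4D, IKKβ(EE), and IRF5-4D with IKKβ(EE), each with 2 arrays that carried the numbers 1 and 3. Reh is an established cell line, and the arrays of a group are described as biological duplicates. What the numbers 1 and 3 stand for, the time between transfection and harvest and the share of transfected cells are not given in the sources used here.

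The deposited values are log2 expression values, 1 per probe set and array. Per the submitters' processing notes they were made with RMA, which corrects for background, quantile-normalizes between arrays and summarises the probes of a probe set; its software version and chip definition are not given in the sources used here. The log2 scale was checked on the values: array medians were at most 5.14, and no gene was centred. Raw array images and probe intensities were not used here.

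The table held 54675 probe sets. The 62 Affymetrix control probe sets and 13522 other probe sets without exactly 1 symbol under the platform annotation of 2016 were left out of the gene-level fit, which left 41091 probe sets. Symbols were compared with a RefSeq table through the Entrez identifiers, which were found there for 41037 probe sets, and 0 symbols changed. Of 19775 genes, 10523 had more than 1 probe set, and each gene was represented by the probe set with the highest mean over all 8 arrays. No filter on level was applied. The lower quartile of an array lay between 3.67 and 3.73, and levels near it are not shown to lie above background, so the size of a change from them is uncertain. Values of probe sets ending in _x_at, which may bind several transcripts, and of the HLA and immunoglobulin families are uncertain.

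Differences were tested in limma 3.58.1 under R 4.3.3 with lmFit and eBayes, with trend and robust options off. A single model of group means was fitted to all 8 arrays, with 4 residual and 5.09 prior degrees of freedom and a prior variance of 0.0201. Its contrasts were each construct and the combination against mock, the combination against each single construct, and the interaction, which is the combination minus both single constructs plus mock on the log2 scale. P values were adjusted by the Benjamini-Hochberg method over all genes, and a gene was called at an adjusted p under 0.05. Changes are log2 differences with the moderated standard error (SE), and group values are means with the SD of 2 arrays. The median SE was 0.14 for a comparison of 2 groups and 0.199 for the interaction. For the probe sets of IRF5 and IKBKB the same model was fitted to every probe set.

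The design, the alternatives, the rule for naming genes and 17 gene lists were fixed before the data were examined. The lists were NF-κB targets, interferon-stimulated genes, cytokines and chemokines, genes associated with Hodgkin lymphoma, B cell identity genes, precursor B cell genes, AP-1 and immediate early genes, apoptosis regulators, cell cycle genes, MHC class I and antigen processing genes, MHC class II genes, stress response genes, p53 targets, markers of T and NK cells, of myeloid cells and of stromal and epithelial cells, and reference genes. They come from general knowledge of the field, and some genes stand in several. Each list was tested with camera at a preset correlation of 0.01 in the contrasts against mock and the interaction, adjusted over the 17 lists of a contrast. Counts adjusted over the list alone used the p values of the list's members only.

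The text names the transfected genes, the 10 largest rises and 6 largest falls among called genes of each contrast against mock (where the values of both groups also had to be separate) and of the interaction. It also names up to 4 called members of each list with the largest change, or 2 as values where none was called. For the combination against each single construct the rule names the 5 largest rises and 3 largest falls. Not every gene under the rule is printed, and genes chosen after their values were seen are said to be so.

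The alternatives were the mean of all probe sets of a gene, leaving out _x_at probe sets, every probe set on its own, only genes above the median level, median centring, another quantile normalization, limma with trend, with robust variance and with array weights, a block for the replicate number, a fit of only the 2 groups compared, calls that also needed a 2-fold change, an adjusted p under 0.1, leaving out each array in turn, and for lists camera with an estimated correlation and fry. A fit without 1 array leaves a group with 1 array, which is then assumed to vary like the others. The sharing of mock arrays was examined with 100 simulations of unchanged groups against the same controls, and with 1 mock array for each comparison.

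The procedure was tested on simulated data with 19775 genes, 20 draws and 200 changed genes. For the combination against mock it recovered 4% of changes of 0.5 log2 units, 78.7% of changes of 1, 98.9% of changes of 2 and 100% of changes of 4, and 4.25% of calls were false. For the interaction it recovered 0.8%, 33.1%, 94% and 99.9%, and 5.48% of calls were false. Contrasts without simulated changes gave 0.05 and 0.1 calls per draw, and 0 lists were called per draw. All genes were drawn independently, with variances from the fitted prior. The draws therefore do not check camera where members of a list are correlated, and in the data the estimated correlation reached 0.371 (cell cycle genes).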

Results

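Gene expression was measured in Reh cells, an established line derived from a precursor B-cell acute lymphoblastic leukaemia, on Affymetrix U133 Plus 2.0 oligonucleotide arrays. The cells had been transfected with control constructs (mock), with IRF5-4D, with IKKβ(EE) or with both constructs together. IRF5 is a transcription factor of the interferon regulatory factor family, and IKKβ, the product of IKBKB, is the kinase that releases NF-κB from its inhibitors. The submitters describe both constructs as constitutively active forms. Each of the 4 groups held 2 arrays, described as biological duplicates and numbered 1 and 3, which made 8 arrays in all. The deposited values were log2 RMA expression values, with array medians of at most 5.14 over all probe sets. The 2 arrays of a group correlated at 0.994 to 0.997 across 19775 genes, and the number of arrays limits the precision. In a principal component analysis, component 1 held 41.8% of the variance. On it the combination arrays lay at 38.06 and 28.16, the mock arrays at -23.03 and -22.32, and the arrays of the single constructs between -8.84 and -2.39.

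The transfected genes were examined first. Of 3 probe sets for IKBKB, the one that responded read 4.43 ± 0.53 (SD, n = 2, log2) in mock cells and 11.8 ± 1.12 with IKKβ(EE), a difference of 7.35 (SE 0.59) or 163-fold with a limma adjusted p of 0.00129 in the fit of every probe set. With 1 array left out the difference ranged from 6.56 to 8.15. In the combination it read 10.2 ± 1.25, which was 5.79 (SE 0.59) or 55.4-fold above mock with an adjusted p of 0.000932, and from 4.91 to 6.68 with 1 array left out. With IRF5-4D alone it read 4.64 ± 0.06. The difference between the combination and IKKβ(EE) alone was -1.56 (SE 0.59), which did not pass limma's test (adjusted p = 0.354). The probe set read 11.11 against 12.57 on the arrays numbered 1 and 9.33 against 10.98 on those numbered 3. The SE contains the gap between arrays 1 and 3, which was 1.59 with IKKβ(EE) and 1.78 in the combination. A lower construct level in the combination is therefore not excluded. The other IKBKB probe sets differed from mock by 0.14 and 0.028 with IKKβ(EE), and neither passed. Of 3 probe sets for IRF5, the one with the highest level read 0.20 (SE 0.13) above mock with IRF5-4D (adjusted p = 0.975), and another read 0.57 (SE 0.17) above mock (adjusted p = 0.701). In the combination the former rose by 0.92 (SE 0.13, adjusted p = 0.00586). It was also 0.72 (SE 0.13, limma adjusted p = 0.0379) higher there than with IRF5-4D alone. The other IRF5 probe sets differed by -0.074 and 0.23 in that comparison, and neither passed. Whether these probe sets lie in the transfected IRF5 sequence is not given in the sources used here, so they do not check the IRF5-4D label.

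**Figure D1:**
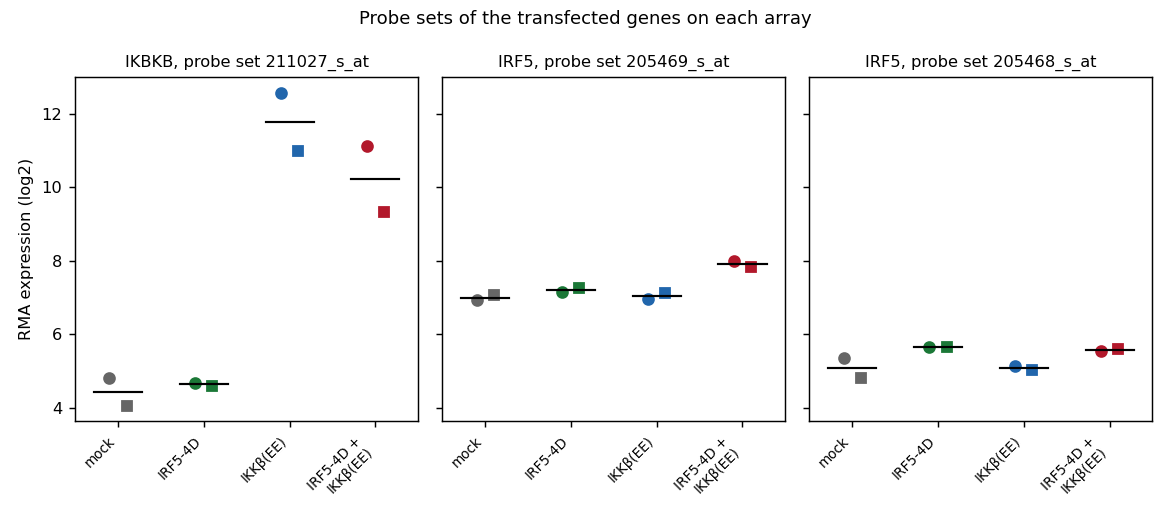
RMA expression (log2) of probe sets of IKBKB and IRF5 on each of the 8 arrays, with circles for arrays numbered 1, squares for arrays numbered 3 and a bar at each group mean. The responding IKBKB probe set lay at 10.98 and 12.57 with IKKβ(EE) and at 4.06 and 4.80 in mock cells, while the IRF5 probe sets moved by less than 1 log2 unit.

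The comparison of IRF5-4D with mock asks what active IRF5 does to expression in these cells. The largest rise was in CCL4, a chemoattractant of monocytes and T cells, which went from 5.38 ± 1.27 (SD, n = 2) in mock cells to 12.7 ± 0.17, a rise of 7.35 (SE 0.57) or 163-fold with a limma adjusted p of 0.000513. Without mock replicate 3 or mock replicate 1 this log2 value was 6.45 or 8.24. CXCL11, an interferon-inducible ligand of CXCR3, rose by 3.72, CCL5 by 3.70, CCL8 by 3.37 and CCL2 by 2.90 on the log2 scale. RIN2, a RAB5 effector, rose by 4.61 (SE 0.28) from 3.80 in mock cells, near the lower quartile of the arrays, and IL1RN, a secreted antagonist of interleukin-1 signalling, rose by 3.59 (SE 0.22, adjusted p = 0.000139). NAPSB rose by 3.66, FRMD3 by 3.30 and DKK1, a secreted inhibitor of WNT signalling, by 3.16. In all 63 genes changed at the adjusted p threshold of 0.05. Of these 62 were higher and 1 was lower. The gene that fell was GIMAP4, a GTPase of lymphocytes, which fell by 1.26 (SE 0.17, adjusted p = 0.015).

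Of 58 measured cytokines and chemokines, 6 rose, 0 fell and 52 did not pass with IRF5-4D, and 10 rose when adjusted over the list alone (camera adjusted p = 1.33e-08, and adjusted p = 0.205 with an estimated correlation). Of 46 interferon-stimulated genes 3 rose, 5 when adjusted over the list alone (camera adjusted p = 1.68e-07, and adjusted p = 0.168 with an estimated correlation). These were IFIT1, an inhibitor of viral translation, by 1.66 (SE 0.18), its relative IFIT5 by 1.25 and the antiviral GTPase MX1 by 1.08. Of 35 NF-κB targets 3 rose, 5 when adjusted over the list alone (camera adjusted p = 2.02e-07, and adjusted p = 0.271 with an estimated correlation). The lymph node homing receptor CCR7 rose by 2.87 (SE 0.38), the urokinase gene PLAU by 2.22 and the costimulatory receptor CD40 by 1.67. Of 47 genes associated with Hodgkin lymphoma 4 rose, 5 when adjusted over the list alone, among them lymphotoxin alpha (LTA) by 1.96 (camera adjusted p = 8.87e-05, and adjusted p = 0.414 with an estimated correlation). Of 15 MHC class II genes 1 rose, 8 when adjusted over the list alone (camera adjusted p = 2.3e-10, and adjusted p = 0.168 with an estimated correlation). It was HLA-DQA1, by 2.70 (SE 0.41), a value that is uncertain because the gene belongs to a polymorphic family and its other probe sets ranged down to -0.082. FCRLA, an Fc receptor-like protein of germinal centre B cells, rose by 2.89 (SE 0.19). It was the 1 of 38 B cell identity genes that rose, and 1 also when adjusted over the list alone (camera adjusted p = 0.000776, and adjusted p = 0.205 with an estimated correlation). The cyclin CCND2 rose by 1.85 (SE 0.30, adjusted p = 0.0482). It was the 1 of 41 cell cycle genes that rose, and 1 also when adjusted over the list alone (camera adjusted p = 1.5e-05, and adjusted p = 0.414 with an estimated correlation). The list of MHC class I and antigen processing genes had 0 of 18 members past the test in limma, and 0 when adjusted over the list alone. The peptide transporter TAP1 read 0.51 (SE 0.14) and the median was 0.081 (camera adjusted p = 0.0262, and adjusted p = 0.205 with an estimated correlation).

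The remaining lists were not called with IRF5-4D (camera adjusted p from 0.118 to 0.601). The inducible heat shock gene HSPA6 rose by 1.89 (SE 0.12) as 1 of 20 stress response genes, the granzyme gene GZMA by 1.97 (SE 0.30) as 1 of 24 T and NK cell markers, and FCER1G, the common gamma chain of Fc receptors, by 1.80 (SE 0.21) as 1 of 22 myeloid markers. Each of these lists also had 1 member higher when adjusted over the list alone. None of 25 precursor B cell genes, 31 AP-1 and immediate early genes, 28 apoptosis regulators, 20 p53 targets and 14 reference genes passed in limma, over all genes or adjusted over the list alone. Of all genes 1017 had an unadjusted p under 0.05 in limma, close to the number that this threshold gives among 19775 unchanged genes. Of 20 stromal and epithelial markers 0 passed over all genes, and 1 was higher and 1 lower when adjusted over the list alone. The actin ACTA2 read -0.81 (SE 0.15, adjusted p = 0.0981 over all genes) and the cadherin CDH1 read 1.72 (SE 0.44). Median, mean and test differed in sign for the precursor B cell genes (median -0.027, mean 0.007, test up), apoptosis regulators (median -0.027, mean 0.049, test up), myeloid markers (median -0.014, mean 0.054, test up) and p53 targets (median -0.027, mean -0.028, test up). The count of 63 genes became 24 without IRF5-4D replicate 1, 29 without IRF5-4D replicate 3 and 34 without mock replicate 1. The 8 called lists became 4 without mock replicate 3 and 0 with an estimated correlation or with fry. Of 24 named genes that passed, 11 kept the call in each of the 8 fits that left out 1 array: CCL2, CCL4, CCL5, CCL8, DKK1, FCRLA, FRMD3, HSPA6, IL1RN, NAPSB and RIN2. With the mean of all probe sets of a gene RIN2 read 2.38, IL1RN 1.07 and HSPA6 1.26 and kept the call, while PLAU (1.26), CCND2 (0.58) and HLA-DQA1 (0.88) lost it, as did CD40 at 1.98 and GZMA at an unchanged 1.97.

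The comparison of IKKβ(EE) with mock asks the same of active IKKβ. The largest rise was in HLA-DQA1, an MHC class II chain, from 4.31 ± 0.83 (SD, n = 2) to 11.4 ± 0.39, a difference of 7.06 (SE 0.41) or 133-fold with a limma adjusted p of 0.000211, although another of its 3 probe sets read -0.01. RNF144B, an E3 ubiquitin ligase, rose by 5.38 (SE 0.23) or 41.6-fold, and LAMP3, a lysosomal protein of mature dendritic cells, rose by 4.54 (SE 0.38) or 23.3-fold. EBI3, a subunit of the cytokines IL27 and IL35, rose by 3.38 (SE 0.34), CCR7 by 3.32 (SE 0.38), the B cell surface protein MS4A1 (CD20) by 3.15 (SE 0.46), the kinase gene SGK1 by 3.11 (SE 0.39), the anti-apoptotic BCL2A1 by 3.07 (SE 0.46) and CCL2 by 2.87 (SE 0.16). IGLC1, an immunoglobulin lambda constant gene, read 3.12 (SE 0.20) higher on a probe set shared with related genes, and its call was lost when such probe sets were left out. In limma 102 genes passed the adjusted p threshold of 0.05, of which 102 were higher and 0 were lower. With 1434 genes at an unadjusted p under 0.05, limma after another quantile normalization called 103 higher and 1 lower, and at an adjusted p under 0.1 it called 156 higher and 6 lower.

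NF-κB targets and MHC class II genes held the largest shares of members that rose with IKKβ(EE). Of 35 NF-κB targets 10 rose, 18 when adjusted over the list alone, and the median change was 0.55 (camera adjusted p = 2.27e-27, and adjusted p = 0.0608 with an estimated correlation). Examples were CCR7, BCL2A1, PLAU by 2.59 (SE 0.27) and the adhesion molecule ICAM1 by 2.51 (SE 0.34). Of 15 MHC class II genes 6 rose, 11 when adjusted over the list alone, and the median change was 0.73 (camera adjusted p = 1.1e-24, and adjusted p = 0.0245 with an estimated correlation). Beside HLA-DQA1 these included HLA-DQB1 by 1.55 (SE 0.14), whose call was lost without cross-hybridising probe sets, and the peptide-loading genes HLA-DMB by 1.21 (SE 0.12) and HLA-DOA by 0.87 (SE 0.11). Of 18 MHC class I and antigen processing genes 2 rose, 4 when adjusted over the list alone (camera adjusted p = 3.49e-09, and adjusted p = 0.0245 with an estimated correlation). TAP1 rose by 1.09 (SE 0.14) and the peptide-loading protein TAPBP by 0.74 (SE 0.12). Of 46 interferon-stimulated genes 1 rose, LAMP3, and 7 when adjusted over the list alone. Of the 46, 41 lay above 0 and the median was 0.24 (camera adjusted p = 2.44e-12, and adjusted p = 0.0245 with an estimated correlation). Of 47 genes associated with Hodgkin lymphoma 7 rose, 19 when adjusted over the list alone (camera adjusted p = 2.21e-15, and adjusted p = 0.14 with an estimated correlation), among them the receptor TNFRSF9 (4-1BB) by 2.01 (SE 0.29). Of 58 cytokines and chemokines 5 rose, 9 when adjusted over the list alone (camera adjusted p = 2.46e-07, and adjusted p = 0.188 with an estimated correlation), including the neutrophil chemokine CXCL8 by 2.33 (SE 0.39) and CD70, a ligand of CD27, by 1.82 (SE 0.16).

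Of 28 apoptosis regulators 3 rose with IKKβ(EE), 4 when adjusted over the list alone (camera adjusted p = 4e-05, and adjusted p = 0.188 with an estimated correlation). They were BCL2A1, which protects cells from death, the death receptor FAS by 2.47 (SE 0.35) and the death-promoting BCL2L11 by 0.97 (SE 0.16). Of 20 p53 targets 2 rose, 5 when adjusted over the list alone (camera adjusted p = 2.14e-09, and adjusted p = 0.0969 with an estimated correlation), namely FAS and TP53INP1 by 1.43 (SE 0.18). The other lists were not called (camera adjusted p from 0.064 to 0.678). In them the orphan nuclear receptor NR4A3 rose by 1.67 (SE 0.15) as 1 of 31 AP-1 and immediate early genes, CCND2 by 2.04 (SE 0.30) as 1 of 41 cell cycle genes, MS4A1 as 1 of 38 B cell identity genes and ACTA2 by 1.26 (SE 0.15) as 1 of 20 stromal and epithelial markers, with 3, 1, 3 and 1 higher when adjusted over the list alone. None of 25 precursor B cell genes passed over all genes, with SMAD1 at 0.61 (SE 0.12, adjusted p = 0.0836) and FLT3 at -0.59 (SE 0.13, adjusted p = 0.161), and 2 were higher and 1 lower when adjusted over the list alone. The 20 stress response genes, 24 T and NK cell markers, 22 myeloid markers and 14 reference genes had 0 members past the test in limma, and 0 when adjusted over the list alone. For the stromal and epithelial markers the median was -0.026, the mean 0.042 and the test upward.

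The count of 102 genes with IKKβ(EE) became 30 without IKKβ(EE) replicate 1, 60 without IKKβ(EE) replicate 3, and 66 without either array of IRF5-4D. It was 56 with the mean of all probe sets of a gene, and the 8 called lists became 3 with an estimated correlation and 4 with fry. Of 26 named genes that passed, 9 kept the call in each of the 8 fits that left out 1 array: CCL2, CD70, HLA-DQA1, HLA-DQB1, IGLC1, LAMP3, NR4A3, PLAU and RNF144B. With the mean of all probe sets of a gene HLA-DQA1 read 2.36, RNF144B 2.38, IGLC1 0.82 and PLAU 1.67 and kept the call. MS4A1 (1.66), TNFRSF9 (0.82), NR4A3 (0.65), BCL2L11 (0.61), CCND2 (0.69), HLA-DOA (0.48), TP53INP1 (0.48) and ACTA2 (0.46) lost it in that fit, as did BCL2A1, CXCL8 and TAPBP with values moved by less.

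**Figure D2:**
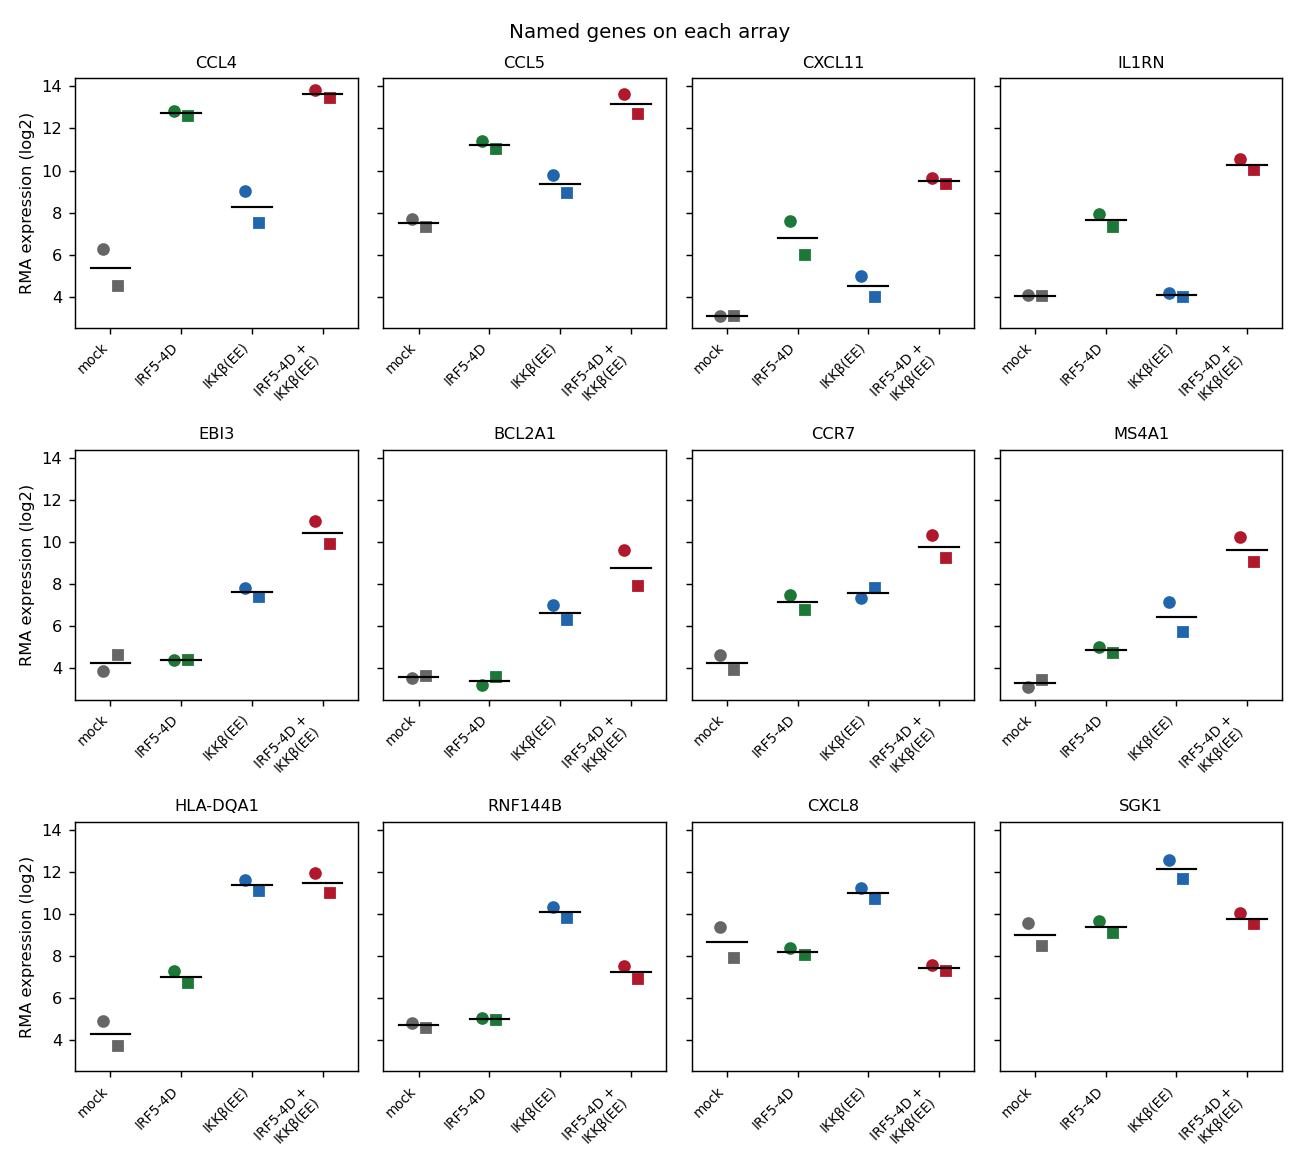
RMA expression (log2) of 12 named genes on each of the 8 arrays, with circles for arrays numbered 1, squares for arrays numbered 3 and a bar at each group mean. CCL4 and IL1RN rose with IRF5-4D, RNF144B and EBI3 rose with IKKβ(EE), and CXCL8 was 3.56 log2 units lower in the combination than with IKKβ(EE) alone (estimate -3.56).

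The combination of IRF5-4D and IKKβ(EE) was then set against mock. CCL4 rose by 8.26 (SE 0.57) or 306-fold, with log2 values of 7.36 without mock replicate 3 and 9.15 without mock replicate 1. HLA-DQA1 rose by 7.16 (SE 0.41) or 143-fold on the probe set used, although another probe set read -0.10, and SRGN, the proteoglycan of secretory granules, went from 6.44 ± 0.70 (SD, n = 2) to 13.4 ± 0.29, a rise of 6.98 (SE 0.30) or 127-fold. CXCL11 rose by 6.41 (SE 0.46), MS4A1 by 6.35 (SE 0.46), IL1RN by 6.24 (SE 0.22), EBI3 by 6.22 (SE 0.34), RIN2 by 5.95 (SE 0.28), CCL5 by 5.64 (SE 0.34) and HSFX3 by 5.58 (SE 0.27). The largest fall was in NPY, the neuropeptide Y gene, which fell by 3.08 (SE 0.61). It read -1.98 without combination replicate 1 and -4.17 without combination replicate 3. The probe set annotated to the ribosomal RNA precursor gene RNA45SN5 fell by 2.19 (SE 0.30), and RASSF10 fell by 2.03 (SE 0.17). DPF3, a subunit of chromatin remodelling complexes, fell by 2.02, the transcription factor gene SOX1 fell by 1.59 and CD247, the zeta chain of the T cell receptor, fell by 1.56. In limma 625 genes changed at the adjusted p threshold of 0.05, 526 higher and 99 lower, and of these 307 rose and 22 fell by at least 2-fold.

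Of 35 NF-κB targets 15 rose in the combination, 19 when adjusted over the list alone, with a median change of 0.92 (camera adjusted p = 4.89e-19, and adjusted p = 0.0927 with an estimated correlation). CCR7 rose by 5.52 (SE 0.38), BCL2A1 by 5.19 (SE 0.46), PLAU by 4.76 (SE 0.27) and the signalling adaptor TRAF1 by 3.74 (SE 0.30). Of 46 interferon-stimulated genes 17 rose, 25 when adjusted over the list alone, and 44 lay above 0 (camera adjusted p = 5.92e-23, and adjusted p = 0.019 with an estimated correlation). Among them were LAMP3 by 4.58 (SE 0.38), the exonuclease gene ISG20 by 2.40 (SE 0.42), IFI44L by 2.13 (SE 0.30) and viperin (RSAD2) by 2.09 (SE 0.42). Of 58 cytokines and chemokines 20 rose, with 25 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.17e-16, and adjusted p = 0.0898 with an estimated correlation). Of 47 genes associated with Hodgkin lymphoma 18 rose, 26 when adjusted over the list alone, with a median change of 0.65 (camera adjusted p = 4.82e-19, and adjusted p = 0.099 with an estimated correlation). Of these 47, 26 also stand in another list, among them EBI3, CCL5, CCR7 and BCL2A1. Of 15 MHC class II genes 12 rose, 12 when adjusted over the list alone (camera adjusted p = 9.41e-17, and adjusted p = 0.052 with an estimated correlation), including HLA-DQB1 by 1.70 (SE 0.14), whose call was lost without cross-hybridising probe sets, HLA-DOB by 1.64 (SE 0.26) and HLA-DOA by 1.12 (SE 0.11). Of 18 MHC class I and antigen processing genes 5 rose, with 13 higher and 2 lower when adjusted over the list alone (camera adjusted p = 1.16e-08, and adjusted p = 0.0266 with an estimated correlation). TAP1 by 1.96 (SE 0.14), TAPBP by 1.01 and TAP2 by 0.69 were among them, and HLA-F by 1.07 on a probe set that may also bind related genes.

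Of 38 B cell identity genes 5 rose and 1 fell, with 7 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00112, and adjusted p = 0.17 with an estimated correlation). MS4A1 led, followed by FCRLA by 2.86 (SE 0.19), the SRC-family kinase gene LYN by 2.01 (SE 0.18) and the coreceptor CD72 by 1.19 (SE 0.17). None of 25 precursor B cell genes passed in limma, with LIG4 at 0.58 (SE 0.13, adjusted p = 0.0556) and the pre-B cell gene VPREB3 at 0.49 (SE 0.15, adjusted p = 0.124), and 1 was higher when adjusted over the list alone. At the same time 3167 of all genes had an unadjusted p under 0.05. Of 31 AP-1 and immediate early genes 5 rose, with 8 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.000323, and adjusted p = 0.459 with an estimated correlation). They included the MAP kinase phosphatases DUSP4 by 4.06 (SE 0.26) and DUSP5 by 2.16 (SE 0.40). DUSP5 read 1.344 without combination replicate 1 and 2.975 without combination replicate 3. The transcription factor genes MAFF, by 3.01 (SE 0.58), and BATF3, by 1.14 (SE 0.12), rose as well. Of 28 apoptosis regulators 4 rose, with 7 higher and 1 lower when adjusted over the list alone (camera adjusted p = 4.06e-05, and adjusted p = 0.186 with an estimated correlation). Of these BCL2A1 and CFLAR, which rose by 3.23 (SE 0.24), inhibit cell death. FAS, which rose by 2.53 (SE 0.35), and TNFSF10 (TRAIL), which rose by 1.28 (SE 0.24), promote it. TNFSF10 read 0.825 without combination replicate 1 and 1.725 without combination replicate 3. Of 20 p53 targets 2 rose, 3 when adjusted over the list alone (camera adjusted p = 0.00121, and adjusted p = 0.27 with an estimated correlation). These were FAS and the cell cycle inhibitor CDKN1A, which rose by 0.95 (SE 0.19). Of 41 cell cycle genes 1 rose and 1 fell, over all genes and when adjusted over the list alone, and the median was -0.20 (camera adjusted p = 0.000682 downward, and adjusted p = 0.538 with an estimated correlation). CCND2 rose by 4.69 (SE 0.30) and the replication helicase gene MCM5 fell by 0.63 (SE 0.13).

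Markers of other cell types, precursor B cell genes, stress response genes and reference genes were not called as lists in the combination (camera adjusted p from 0.356 to 0.917). Single members changed: FCER1G rose by 4.42 (SE 0.21) as 1 of 22 myeloid markers, CDH1 by 4.96 (SE 0.44) as 1 of 20 stromal and epithelial markers (its other probe set read -0.062), and the transcription factor gene GATA3 by 2.62 (SE 0.32) and NKG7 by 1.34 (SE 0.19) among 24 T and NK cell markers, where CD247 fell. Adjusted over the list alone, these lists had 1 higher, 1 higher, and 2 higher and 1 lower. Of 20 stress response genes HSPB1 rose by 1.12 (SE 0.22) and HSPA6 by 1.01 (SE 0.12), with 2 higher and 2 lower when adjusted over the list alone. HSPB1 read 0.738 without combination replicate 1 and 1.505 without combination replicate 3. Of 14 reference genes 0 passed in limma and 0 when adjusted over the list alone, with TBP at -0.26 (SE 0.13). Median, mean and test differed in sign for the T and NK cell markers (median -0.11, mean 0.051, test down), myeloid markers (median -0.057, mean 0.17, test up), stromal and epithelial markers (median -0.046, mean 0.22, test up) and reference genes (median 0.015, mean -0.018, test down). The count of 625 genes became 355 without mock replicate 1 and 360 without combination replicate 1. It was 280 when mock and combination alone were fitted, and the 11 called lists became 2 with an estimated correlation. With fry the AP-1 and immediate early genes, cell cycle genes and p53 targets lost the call (fry adjusted p = 0.161, 0.327 and 0.113). The other called lists kept it. Of 51 named genes that passed, 37 kept the call in each of the 8 fits that left out 1 array, and NPY, DPF3, CD247, MCM5, MAFF, ISG20 and RSAD2 were among the 14 that did not. With the mean of all probe sets of a gene HLA-DQA1 read 2.34, MS4A1 4.08, IL1RN 2.67, RIN2 3.21, TRAF1 2.43, CFLAR 1.61, CCND2 2.13, HLA-DOA 0.61, CDH1 2.45, SOX1 -0.55 and CD247 -0.84 and kept the call. DPF3 (-1.10), TAP2 (0.45) and HLA-DOB (0.78) lost it, as did NPY, MAFF and MCM5 with values moved by less.

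**Figure D3:**
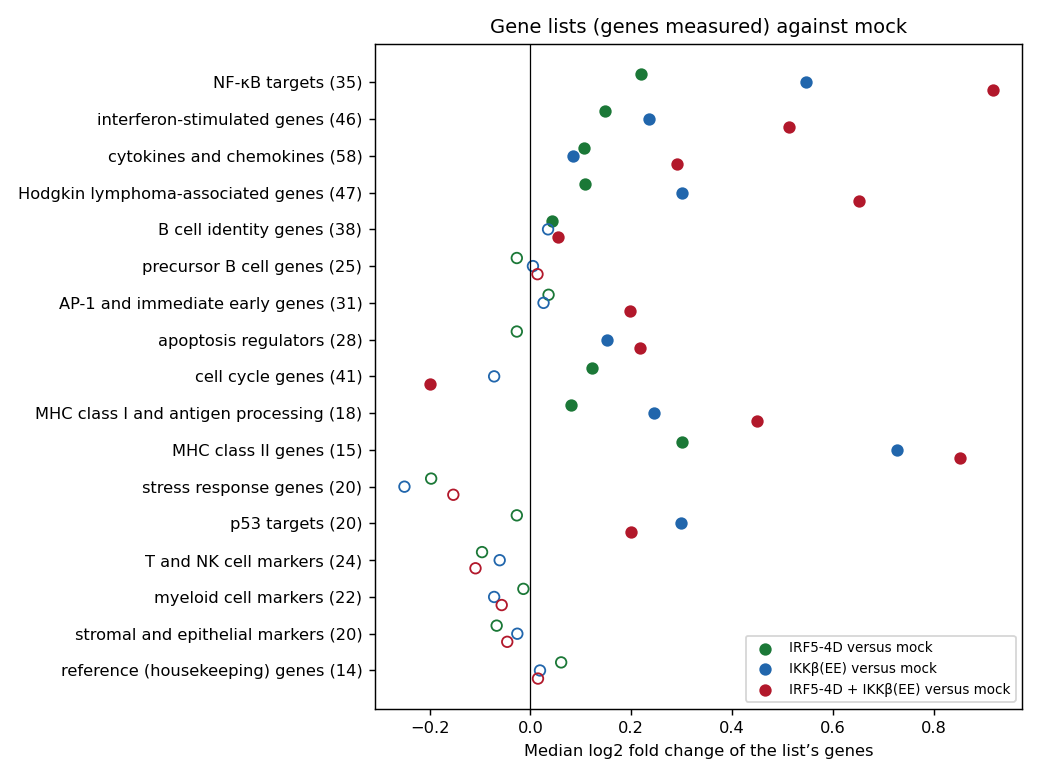
Median log2 fold change against mock of the measured members of 17 gene lists, for IRF5-4D, IKKβ(EE) and the combination, with filled points where camera's adjusted p was under 0.05 at its preset correlation and open points elsewhere. The NF-κB targets stood at 0.22, 0.55 and 0.92 and the cell cycle genes at 0.12, -0.072 and -0.20.

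The overlap between comparisons was counted next. CCL2, CCR7, PLAU, CCND2 and HLA-DQA1 were among 14 genes that rose with each single construct, where 0.32 shared genes would come from independent lists. The combination shared 57 of its 526 risen genes with IRF5-4D alone and 66 with IKKβ(EE) alone, where independent lists would give 1.65 and 2.71, and GIMAP4 was the 1 fall that it shared with IRF5-4D. All these comparisons use the same mock arrays. In 100 simulations of unchanged groups against them, at most 0.03 shared calls arose on average. Unchanged groups give almost no calls, so this could not show how far shared mock arrays add to overlaps among genes that did change. The correlation of log2 fold changes between the single constructs was 0.417 across genes, below the 0.499 that shared mock arrays gave without any effect, and the covariance was 0.0242 against 0.0165. For the combination with IRF5-4D the correlation was 0.622 and the covariance 0.0571 against 0.0165, and with IKKβ(EE) 0.569 and 0.0576 against 0.0166. In a check added after the result was seen, each comparison had 1 mock array to itself, in both orders. The correlation was then 0.023 and 0.054 between IRF5-4D and IKKβ(EE), 0.273 and 0.354 between IRF5-4D and the combination, and 0.272 and 0.316 between IKKβ(EE) and the combination. The 14 shared rises became 5 without IRF5-4D replicate 1, 6 without IRF5-4D replicate 3, 6 without IKKβ(EE) replicate 1, 8 without mock replicate 1, 6 without mock replicate 3 and 3 with the mean of all probe sets.

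The combination was also tested against each construct alone. Against IRF5-4D alone, EBI3 was higher by 6.07 (SE 0.34), BCL2A1 by 5.38 (SE 0.46), HSFX3 by 5.17 (SE 0.27), SRGN by 4.84 (SE 0.30) and MS4A1 by 4.76 (SE 0.46). RNA45SN5 fell by 2.77 (SE 0.30), the chemokine CCL8 fell by 2.15 (SE 0.23) and the membrane protein gene EMP1 fell by 1.82 (SE 0.33). In limma 279 genes differed, 242 higher and 37 lower in the combination. Against IKKβ(EE) alone, IL1RN was higher by 6.20 (SE 0.22), RIN2 by 5.89 (SE 0.28), HSFX3 by 5.46 (SE 0.27), CCL4 by 5.40 (SE 0.57) and CXCL11 by 4.98 (SE 0.46). CXCL8 fell by 3.56 (SE 0.39), RNA45SN5 fell by 3.04 (SE 0.30) and RNF144B fell by 2.85 (SE 0.23). Here 340 genes differed, 271 higher and 69 lower. Of the 526 genes that rose over mock in the combination, 128 were also higher than with each construct alone, and 417 had passed against mock with neither construct alone. A gene called in 1 comparison and not in another is not thereby shown to differ between them, and the interaction tests that difference. The count of 279 became 70 without either array of IRF5-4D and 173 without combination replicate 1. That of 340 became 116 without IKKβ(EE) replicate 1, 108 without IKKβ(EE) replicate 3 and 189 without combination replicate 1. With the mean of all probe sets of a gene EMP1 read -0.72 and lost the call against IRF5-4D, and against IKKβ(EE) IL1RN read 2.56, RIN2 3.15 and RNF144B -1.66 and kept it.

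The interaction asks whether both constructs together did more or less than the sum of their single effects on the log2 scale. In the combination HSFX3 stood at 9.06 ± 0.69 (SD, n = 2) against 3.49 in mock cells, 3.89 with IRF5-4D and 3.60 with IKKβ(EE), an interaction of 5.06 (SE 0.38, limma adjusted p = 0.00575). Values near the lower quartile of the arrays, such as the last 3, are not shown to lie above background, so the size of this interaction is uncertain. The long non-coding RNA LINC01857 had an interaction of 3.79 (SE 0.45), the cortisol-regenerating enzyme HSD11B1 of 3.72 (SE 0.49), TMCC3 of 3.26 (SE 0.47), the fatty acid receptor GPR84 of 3.09 (SE 0.31) and DUSP4 of 3.07 (SE 0.37). Further genes above the sum were TENM2 at 2.88, the interleukin receptor chain IL10RA at 2.82, the transporter subunit SLC51A at 2.75, the RNA-binding protein CPEB2 at 2.70, the chemokine CXCL9 at 2.60 and FCER1G at 2.59. Below the sum lay RNA45SN5 at -3.62 (SE 0.43), RNF144B at -3.16 (SE 0.33), the activin subunit INHBA at -1.66 (SE 0.21) and the divergent transcript AFTPH-DT at -1.84 (SE 0.24). IGLC1 at -2.14 (SE 0.29) and IGLV1-44 at -1.74 (SE 0.25) were read by probe sets shared among immunoglobulin genes. Without such probe sets their interactions were 0.013 and 0.079. In all 25 genes had an interaction, 19 above and 6 below 0.

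**Figure D4:**
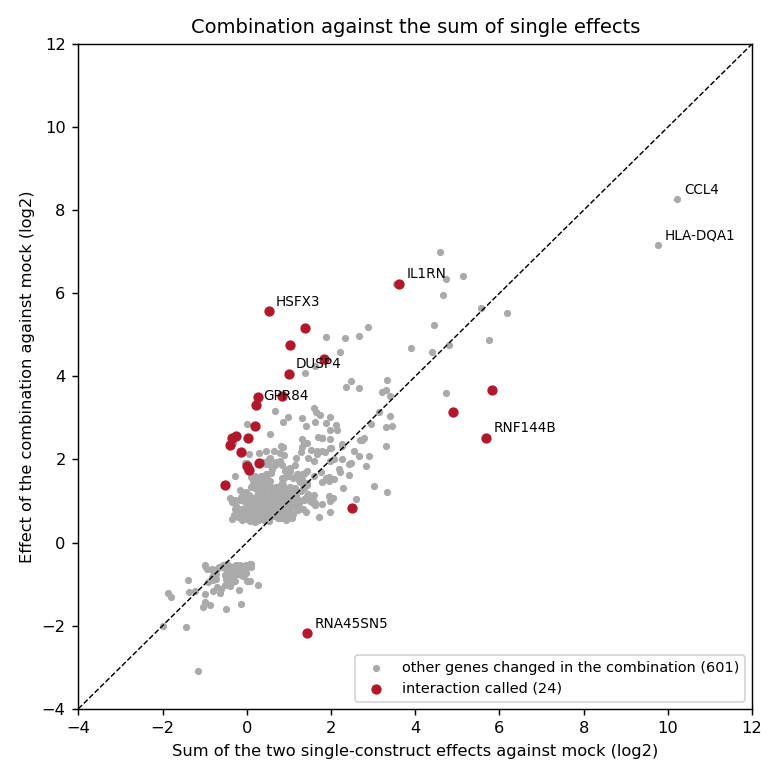
Effect of the combination against mock (log2) plotted against the sum of the effects of IRF5-4D and IKKβ(EE) for the 625 genes that changed in the combination; the dashed line marks equality. The 24 genes in red passed the test of the interaction and the 601 in grey did not, which does not show them to be additive. HSFX3 lay above the line and RNF144B and RNA45SN5 below it.

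Among the lists, 1 of 58 cytokines and chemokines (CXCL9), 1 of 31 AP-1 and immediate early genes (DUSP4) and 1 of 22 myeloid markers (FCER1G) had an interaction. In the other 14 lists 0 members passed in limma, with 1206 of all genes at an unadjusted p under 0.05. Camera called 4 lists at its preset correlation and 0 with an estimated correlation, and fry called 0. The cell cycle genes lay below the sum with a median of -0.30 (camera adjusted p = 1.68e-06, and adjusted p = 0.601 with an estimated correlation), where CCNB1 read -0.90 (SE 0.34) and CCNE2 -0.87 (SE 0.37) and neither passed. The MHC class II genes had a median of -0.22 (camera adjusted p = 0.00119, and adjusted p = 0.601 with an estimated correlation), and HLA-DQA1 read -2.60 (SE 0.58, adjusted p = 0.258). The genes associated with Hodgkin lymphoma had a median of 0.15 (camera adjusted p = 0.0385, and adjusted p = 0.656 with an estimated correlation), where EBI3 read 2.68 (SE 0.48, adjusted p = 0.125) and BCL2A1 2.31 (SE 0.65, adjusted p = 0.472). The cytokines and chemokines had a median of 0.22 (camera adjusted p = 0.0385, and adjusted p = 0.601 with an estimated correlation). Adjusted over the list alone, 12 genes associated with Hodgkin lymphoma were higher and 2 lower, 7 cytokines and chemokines were higher and 3 lower, 5 AP-1 and immediate early genes were higher and 1 lower, 3 interferon-stimulated genes were higher, 2 MHC class II genes were lower and 0 cell cycle genes passed. The other 13 lists were not called (camera adjusted p from 0.0938 to 0.92). Adjusted over the list alone, 2 stress response genes were higher and 1 lower, 2 T and NK cell markers were higher and 1 lower, and 1 apoptosis regulator was higher and 1 lower. In the same way 1 member each was higher among the NF-κB targets, B cell identity genes, myeloid markers and stromal and epithelial markers, 1 each was lower among the precursor B cell genes and p53 targets, and 0 passed among the MHC class I and reference genes. Median, mean and test differed in sign for the NF-κB targets (median -0.05, mean 0.018, test down) and the B cell identity genes (median -0.001, mean 0.048, test up). The interaction rested on few arrays: the count of 25 became 0 without IRF5-4D replicate 3, 2 without IRF5-4D replicate 1, 2 without IKKβ(EE) replicate 1, 3 without IKKβ(EE) replicate 3, 14 without mock replicate 1 and 80 without combination replicate 3. Of 18 named genes, HSFX3 and RNF144B included, 0 kept the call in all 8 such fits. With the mean of all probe sets of a gene CPEB2 (1.37), RNF144B (-1.70), INHBA (-1.04), IGLC1 (-0.39) and IGLV1-44 (-0.28) lost the call, as did LINC01857, HSD11B1, DUSP4, SLC51A, RNA45SN5, AFTPH-DT and CXCL9 with values moved by less or not at all. The 4 called lists became 2 without IRF5-4D replicate 3 and 7 without IKKβ(EE) replicate 1, mock replicate 3 or combination replicate 3.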

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

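The tests of the median over all genes raised by IKKβ(EE), of the ribosomal RNA control probe sets and of RNA integrity were chosen after the result was seen, as were the fits with the IKBKB level as a covariate and the comparison of the IKKβ(EE) arrays.

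In 25 genes the effect of IKKβ(EE) with IRF5-4D differed from its effect without it, by limma's test of the interaction at an adjusted p under 0.05. The difference was above 0 for HSFX3 (5.06), LINC01857 (3.79), HSD11B1 (3.72), TMCC3 (3.26), GPR84 (3.09), DUSP4 (3.07), TENM2 (2.88), IL10RA (2.82), SLC51A (2.75), CPEB2 (2.70), IL1RN (2.62), CXCL9 (2.60), FCER1G (2.59), BHLHE41 (2.49), PCP4 (2.33), ACKR3 (1.90), SERPINE2 (1.83), LOC100128988 (1.68) and SYT3 (1.62), in log2 units. It was below 0 for INHBA (-1.66), IGLV1-44 (-1.74), AFTPH-DT (-1.84), IGLC1 (-2.14), RNF144B (-3.16) and RNA45SN5 (-3.62). IL1RN, BHLHE41, PCP4, ACKR3, SERPINE2, LOC100128988 and SYT3 fall outside the rule for naming genes and are given because all 25 are.

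Among 13522 probe sets left out of the gene-level fit for want of a single gene symbol, limma called 10 against mock with IRF5-4D, 18 with IKKβ(EE) and 124 with the combination. The first 10 and the 18 were all higher, and of the 124 there were 95 higher and 29 lower.

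The first pattern is the group of 19 genes, led by HSFX3, that lay above the sum of the single effects. A floor of the array could hide the effect of a single construct, and 18 of the 19 had a mock level below the median of all genes (94.7%) against 170 of 507 other genes that rose in the combination (33.5%; one-sided Fisher exact p = 6.81e-08). All 19 rose by at least 1.38 over mock, and the 507 were not matched to them in the size of the rise. The Fisher test may therefore partly reflect how the 19 were picked. The low values that a floor needs are there for these 18 genes, and the amount of synergy in them stays open. ACKR3, with a mock level of 6.45 above the median of 6.15, had an interaction 7.18 standard errors above 0. Its mean with IKKβ(EE) was 5.62, below the median, but a floor there would make its interaction smaller, not larger. ACKR3 was picked for its interaction, so this single gene does not decide about a floor. Cooperation of the constructs, the biological explanation that the design offers, stays open and was not tested apart from the interaction.

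The second pattern is that 27 of the 102 genes raised by IKKβ(EE) were lower in the combination than with IKKβ(EE) alone, among them CXCL8 (-3.56), RNF144B (-2.85), SGK1 (-2.34), NR4A3 (-1.51) and INHBA (-1.30), while 12 were higher; SGK1, NR4A3 and INHBA were chosen here after their values were seen. A lower level of the IKKβ construct could account for this, since its probe set differed by -1.56. For the 27 genes the median difference of -1.175 (median SE 0.159) was -1.017 (SE 0.196) with that level as a covariate. With the replicate number as well it was -1.019 (SE 0.233). Between the IKKβ(EE) arrays, whose construct levels differed by 1.59, the median difference was 0.183 (SE 0.225) where the construct level would need 1.198. These tests do not decide whether the construct level was the whole cause. Genes were called against the spread between arrays of a group. Those that followed the construct level within a group were therefore less likely to be called. The covariate fits take their slope from the same spread. Over all 102 genes the median difference was -0.244 (quartiles -0.781 and 0.301). For this wider set a lower construct level and an effect of IRF5-4D cannot be told apart. The combination arrays carried IRF5-4D and also read lower for the IKKβ construct. Members of the set moved both ways. The 102 genes were also picked as high on the IKKβ(EE) arrays, and the combination was compared with those same arrays. That selection alone favours differences below 0, and its share was not tested. Repression by IRF5-4D, the biological explanation, stays open: with IRF5-4D alone 14 of the 27 lay below 0 and 0 passed in limma (lowest adjusted p = 0.0981, ACTA2, chosen after its values were seen), which decides little because 16 had mock levels below the median of all genes, and 4 of the 27 were still called above mock in the combination.

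The third pattern is the fall of the RNA45SN5 probe sets, by 2.26 in the combination against the other 6 arrays (-2.26), with the brighter one at most at 7.89 against at least 9.73 elsewhere. Less ribosomal RNA in the labelled target could lower them. The 18S control probe sets changed by -0.24 and the 28S control probe set by -0.32, with a median of -0.28. The 28S probe set read 13.33 on combination replicate 1 but 12.36 on replicate 3, below the 12.88 to 13.33 of the other arrays. These values argue against a loss of that size on both combination arrays. How far control probe sets at such high levels respond to a loss was not tested. A difference in RNA integrity is argued against by the control probe sets, where actin 3' minus 5' was 1.06 in the combination against 0.98 to 1.37 on the other arrays, and GAPDH 0.22 to 0.24 against 0.20 to 0.30. A lower level of the precursor transcript in cells with both constructs is a hypothesis that stays open; cross-hybridisation of the _x_at probe set alone is argued against, since without it the fall was -1.47 against mock, -1.95 against IRF5-4D and -2.16 against IKKβ(EE) and kept its call, although the interaction (-2.64) did not.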

How the results depend on the processing

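All tests here were planned before the result was seen. Among genes called both in the reported fit and under an alternative, 0 had changed sign (fits of every probe set on its own were not compared in this way). Over the named genes called in the reported fit, with IRF5 and IKBKB added, 2282 values kept direction and side of the threshold under the alternatives. Of the other values 350 lost the call, 2 gained it and 2 reversed. Over the called lists 544 values kept the call and 72 lost it. Genes and lists without a call in the reported fit were not followed, so these numbers do not show how often calls were gained. The reversed values were the interactions of IGLC1 (0.013) and IGLV1-44 (0.079) without _x_at probe sets, where another probe set stands for the gene. With 2 arrays per group, every count of calls depends on single arrays.

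With 1 array left out, counts ranged from 24 to 83 for IRF5-4D against mock, 30 to 116 for IKKβ(EE), 355 to 564 for the combination, 70 to 286 for the combination against IRF5-4D, 108 to 347 for the combination against IKKβ(EE), 0 to 80 for the interaction and 5 to 17 for the rises shared by both single constructs. Called lists ranged from 4 to 9, 8 to 11, 9 to 11 and, for the interaction, 2 to 7. The responding IKBKB probe set ranged from 6.56 to 8.15 with IKKβ(EE) against mock and from 4.91 to 6.68 in the combination. A smaller count is what fewer arrays give, but the cause of the larger ones was not tested.

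The mean of all probe sets gave 56 genes for IKKβ(EE), 9 for the interaction and 3 shared rises. Every probe set on its own gave 100 for IRF5-4D, 1049 for the combination, and 422 and 569 for the combination against IRF5-4D and IKKβ(EE); more probe sets than genes are tested there. Only genes above the median level gave 41 for IRF5-4D, 150 and 179 for the combination against each construct and 0 for the interaction, with fewer genes tested. Another quantile normalization gave 2 lists for the interaction. For these the cause was not tested further. A fit of only the 2 groups compared gave 280 for the combination and 149 and 225 against each construct, with fewer arrays to estimate variance. Requiring 2-fold gave 329, 168 and 206, and an adjusted p under 0.1 gave 162 for IKKβ(EE) (156 higher and 6 lower), 1048, 484 and 547 for the combination and 40 for the interaction, as stricter and looser thresholds must.

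Lists called with an estimated correlation were 0 for IRF5-4D, 3 for IKKβ(EE), 2 for the combination and 0 for the interaction. With fry they were 0 for IRF5-4D, 4 for IKKβ(EE) and 0 for the interaction. In the combination the AP-1, cell cycle and p53 lists lost the call with fry and the other called lists kept it. The cause was not tested. A higher correlation is not the whole of it. The MHC class I list lost its call with IRF5-4D although its estimated correlation of -0.015 lay below the preset 0.01.

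The replicate numbers were not taken to pair the arrays: deviations of arrays with the same number correlated at 0.334, 0.343, 0.223, -0.073, 0.110 and 0.107 over the 6 pairs of groups, not all over 0.1. With a replicate block the counts were 191 for IKKβ(EE) (178 higher and 13 lower), 446 and 511 for the combination against IRF5-4D and IKKβ(EE), 56 for the interaction and 23 shared rises, and every gene called without the block kept its call. Of the called lists, the interaction of genes associated with Hodgkin lymphoma had an adjusted p of 0.0507 with the block in limma's camera, and the others kept the call. Lists not called without the block were not compared one by one.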

Other observations

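The direct comparison of the single constructs was added after the result was seen, and its genes were chosen after their values were seen. IRF5-4D raised FCGR2A, a low-affinity Fc receptor for IgG, to 7.36 ± 0.08 (SD, n = 2) against 4.54 ± 0.07 with IKKβ(EE), a difference of 2.82 (SE 0.11, limma adjusted p = 2.1e-05). The urokinase receptor PLAUR was higher with IRF5-4D by 2.55 (SE 0.26), the chemokine receptor CCR6 by 2.93 (SE 0.46), the stem cell factor receptor KIT by 1.85 (SE 0.17), CD48 by 1.84 (SE 0.20) and NCF1, a subunit of the phagocyte NADPH oxidase, by 1.67 (SE 0.21). RIN2 was higher by 4.55, CCL4 by 4.48, IL1RN by 3.56, CCL8 by 3.40 and FRMD3 by 3.26. With IRF5-4D, RNF144B was lower than with IKKβ(EE) by 5.07 (estimate -5.07, SE 0.23), and LAMP3 (-4.68), HLA-DQA1 (-4.36), BCL2A1 (-3.26), EBI3 (-3.23), FAS (-3.16) and CXCL8 (-2.78) were lower as well. In all, 62 genes were higher and 89 lower with IRF5-4D than with IKKβ(EE).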
